A study of Mus musculus with 26 samples.

How the data were processed

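Hearts came from Cntn2-Cre;Rosa26-tdTomato reporter mice, in which cells that have expressed Cntn2, a cell adhesion gene of the cardiac conduction system, carry the red fluorescent protein tdTomato. Per the labels, 2 assays were run. In the first, tdTomato-positive cells of postnatal days 1, 2 and 4 (P1, P2 and P4) were sorted, tagged by age with MULTI-seq lipid barcodes, pooled and sequenced as 1 10x Genomics single-cell library. The labels put the gate at 0.1 to 0.2% of viable cells. In the second, PFA-fixed cryosections of 8 µm from P4 reporter hearts were profiled with the NanoString GeoMx Digital Spatial Profiler, which counts barcodes cleaved from gene probes inside a chosen region of interest (ROI). The design text states that ROIs were selected for named parts of the conduction system and for adjacent ordinary myocardium, so the groups rest on anatomy as the submitters drew it.

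The GeoMx table held a signal per gene target and ROI, Q3 normalized by the authors, for 12637 targets and a negative probe. Every ROI had the same 75th percentile, 12.9 units. The values of each ROI were whole multiples of 1 step (at least 99.976% of its values to within 0.001), and the step is 12.9 divided by the whole number of counts at the 75th percentile, so counts could be recovered. In 4 working myocardium ROIs (RA, LEPI, IVSB and RV) no target lay at 1 step, and their recovered totals follow from the spacing of values alone. The counting tool and any gene filter of the authors for this assay are not given in the sources used here. The deposited single-cell table held raw UMI counts per gene and cell, and in every cell its sums matched the UMI and gene totals in the authors' per-cell table. That table also gave the percent of UMIs from mitochondrial genes, which the authors had computed, the age of each cell, and a cell type for each cell from their clustering. The submitters' processing notes name Cell Ranger 3.1.0, Seurat 4.0.0 and mm10; their cell filter and any removal of doublets are not given in the sources used here, and no doublet caller was run here.

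ROIs were grouped by their labels. The conduction ROIs covered 10 regions: the sinoatrial node (SAN), compact atrioventricular node (CAVN), bundle of His (HIS), the lower part of the nodal bundle (LNB), the left bundle branch near to and far from the His bundle (PLBB, DLBB), the same for the right bundle branch (PRBB, DRBB), and the Purkinje fibers of the left (LPF) and of the right ventricle (RPF). The 6 working myocardium regions were the right atrial appendage (RA), left endomyocardium (LENDO), left epimyocardium (LEPI), basal and apical interventricular septum (IVSB, IVSA) and right ventricle (RV). Each conduction region had 2 ROIs except CAVN with 1, and each working region had 1. The labels tie no ROI to an animal, so ROIs may share an animal, and p-values over ROIs measure only the spread between ROIs and may be too small.

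Values were analysed as log2 of signal plus 1. A target was tested if at least 2 ROIs exceeded their 75th percentile, which left 7848. Comparisons used limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Where enough regions existed, ROIs were averaged and regions were the units: 10 conduction against 6 working regions, 7 ventricular conduction against 5 working ventricular regions, and 3 nodal against 7 His-Purkinje regions. The other 6 comparisons used all 25 ROIs with 1 mean per region in 16 regions, which leaves 9 residual degrees of freedom. There the lone RA ROI was assumed to vary like the regions with 2 ROIs. Fold changes are differences of mean log2 values, so they can differ from ratios of the mean signals printed beside them.

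Of 25 gene lists written beforehand, 23 had at least 3 tested members and were tested with camera at an inter-gene correlation of 0.01, with the estimated correlation and fry beside it. Camera compares a list with all other genes, and its p-values were adjusted over the lists of a comparison. The tests, lists, groups and the rule for named genes were fixed before the data were examined. That rule names the 8 highest and 8 lowest log2 changes among called genes with a mean above the median of tested genes, up to 4 members with the smallest p of each list described, and Cntn2, Hcn4, Tbx3, Irx3, Gja5, Etv1, Shox2, Isl1, Nppa and Myl2 in every comparison. Of these 10 genes, 9 were tested; Isl1 was not among the targets. The rule also named 1 further gene, which is not reported here. For single-cell types it names the 10 genes of highest fold per type, and for ages up to 8 genes each way that pass a size rule. The text prints a selection of the genes so named.

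Single-cell UMIs were summed per cell type or age and scaled to each total (CPM), with exact 95% Poisson intervals for sums and exact 95% binomial (Clopper-Pearson) intervals for shares. These intervals cover counting error only. With 1 library there are no replicates, so no test was run between types or ages. For ages, a gene was named if it had a fold of at least 2 between P1 and P4 and at least 50 CPM in either. For each of the 5 conduction cell types, the 50 genes with the highest ratio of CPM plus 10 to the other conduction types, among those with at least 50 CPM, formed a marker list, which was tested with camera in the ROIs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and matplotlib 3.10.9 drew the figures.

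Alternatives fixed at the start were a pseudocount of 5, quantile normalization, no filter on low values, leaving out each ROI, single ROIs as units, a block for ROI number within the conduction ROIs, leaving out LNB or both RA and SAN, 20 markers per type, thinned cells, and estimated list correlations. Others were added after seeing the data: edgeR 4.0.16 quasi-likelihood tests on the counts recovered from 21 ROIs, working myocardium thinned to 87635 counts per ROI, subtraction of the negative probe, leaving out both PRBB ROIs, centring of groups, the conduction ROIs without a block, marker lists without atrial, ventricular or sarcomere genes, and estimated correlations for the marker lists. RA, LEPI, IVSB and RV were left out of the count tests because their steps were less certain.

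The limma pipeline was tested on simulated counts at the depth of each ROI. It recovered 63.5% of 2-fold changes in the comparison of 10 with 6 regions and 54.0% in that of 7 with 5, but 23.3% for nodal against His-Purkinje regions. In the ROI-level comparisons the recovery at 2-fold was 1.64% for SAN against the atrioventricular junction, 6.90% for His bundle against bundle branches, 18.5% for Purkinje fibers, 31.0% for left against right, 22.4% for proximal against distal and 0% for SAN against RA, so genes not called there are not shown to be equal. Unchanged genes had a median log2 change of −0.21 in the simulated comparison of 10 with 6 regions at the depth of each ROI, and of −0.001 at equal depth. Gene coordinates are from GENCODE vM21 (GRCm38). Probe targets for tdTomato and Cre follow from the reporter and are not counted as findings. The EGFP target was set aside with them as a transgene target, although the stated genotype names no EGFP.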

Results

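The data covered the cardiac conduction system of neonatal reporter mice by 2 assays. GeoMx profiling at P4 gave 25 ROIs in 16 regions, with 19 ROIs from 10 conduction regions and 6 ROIs from 6 regions of working myocardium. The single-cell library gave 6855 cells, of which 2809 were from P1, 1818 from P2 and 2228 from P4. The ROIs differed in depth by type of tissue. Conduction ROIs held between 40332 (PRBB ROI 1) and 135652 (SAN ROI 2) recovered counts, with a median of 87635. Working myocardium ROIs held between 425077 (LEPI) and 880378 (RA), with a median of 646182. The count at the 75th percentile of targets was 3 to 12 in conduction ROIs and 31 to 72 in working myocardium. A single count was therefore worth 4.29 units of signal in PRBB ROI 1 and 1.07 in SAN ROI 2. The negative probe read 3.54 to 6.32 units in conduction ROIs and 4.62 to 7.27 in working myocardium, and signals near these levels are background. The share of targets above 2 times the negative probe was 26.7 to 51.7% in conduction ROIs and 17.1 to 47.2% in working myocardium. ROIs of the same region had correlations across targets between 0.446 (DLBB) and 0.663 (RPF), where targets are not independent replicates. In all 9 pairs the ROIs of a region differed by about the counting noise (chi-square per degree of freedom 0.778 to 1.05), and none held identical values, so they were kept as separate ROIs.

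**Figure D1:**
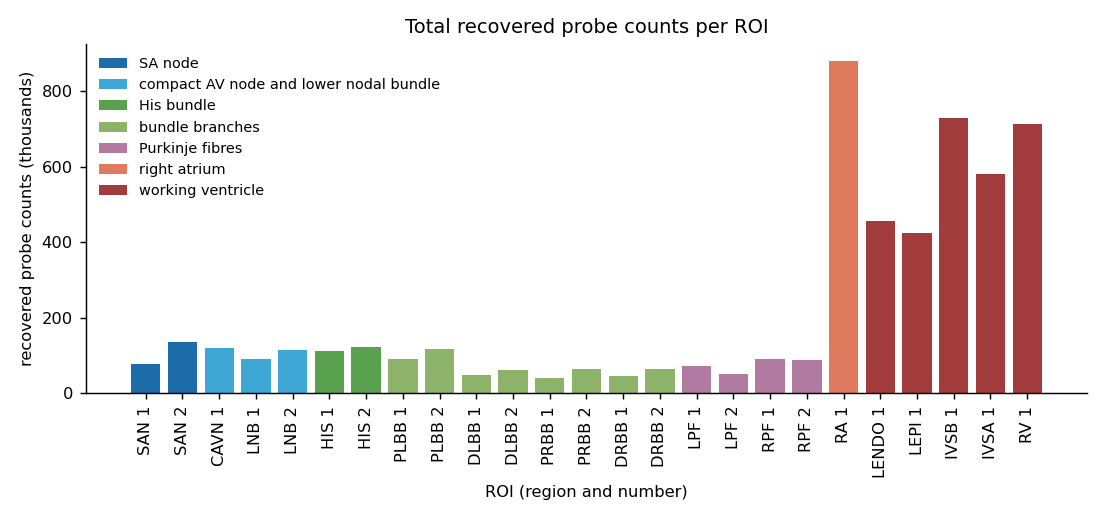
Recovered probe counts (linear axis from 0, scaled as labelled) for each of the 25 ROIs, with bars coloured by component. The 6 working myocardium ROIs lie between 425077 and 880378 counts, all above the conduction ROIs, of which the deepest held 135652; for RA, LEPI, IVSB and RV the counts follow from the spacing of values alone.

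The first comparison asked which genes set conduction tissue apart from ordinary heart muscle, with 10 conduction against 6 working regions as units. Genes of pacemaking and conduction were higher in conduction regions. Hcn4, which encodes the main pacemaker channel (chromosome 9, 58823412 to 58863175, plus strand), had a signal of 26.6 ± 15.6 (SD, n = 10) against 4.85 ± 1.80 (SD, n = 6), a log2 change of 2.10 ± 0.27 (SE) with a limma adjusted p of 2.3e-06. Cacna2d2, a calcium channel subunit (chromosome 9, 107399612 to 107529343, plus strand), read 37.9 ± 21.8 against 6.56 ± 2.48 (log2 change 2.16 ± 0.30, adjusted p = 5.9e-06). Igfbp5, a secreted binding protein of insulin-like growth factors (chromosome 1, 72857932 to 72874884, minus strand), had the largest rise among the genes above the median level, at 5.28-fold (log2 change 2.40 ± 0.24, adjusted p = 9.4e-09). Mb, which encodes the oxygen carrier myoglobin (chromosome 15, 77015487 to 77050670, minus strand), fell from 735 ± 336 in working myocardium to 80.4 ± 57.2 in conduction regions (log2 change −3.38 ± 0.44, adjusted p = 3.5e-06).

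Markers of the reporter lineage and of fast conduction rose. Cntn2 (chromosome 1, 132509427 to 132543256, minus strand), whose promoter drives the Cre, read 18.2 ± 8.83 against 5.59 ± 1.74 (log2 change 1.43 ± 0.26, adjusted p = 0.00036). Etv1, a transcription factor of fast-conducting cells (chromosome 12, 38779380 to 38870484, plus strand), rose by 2.02 ± 0.35 on the log2 scale (adjusted p = 0.000167), Gja5, the connexin of high conductance (chromosome 3, 96904693 to 97077416, plus strand), by 1.41 ± 0.35 (0.00695), and Irx3 by 0.99 ± 0.27 (0.0166). Tbx3 (log2 change 0.02 ± 0.26) and Shox2 (0.14 ± 0.28) were not called, with adjusted p of 0.974 and 0.777. In the His-Purkinje regions Tbx3 read 5.30 ± 1.43 (SD), at the level of the negative probe (3.54 to 6.32), so equal expression is not shown. Nppa (−1.67 ± 0.66, adjusted p = 0.11) and Myl2 (−0.91 ± 0.82, adjusted p = 0.515) varied widely between regions and were not called either.

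**Figure D2:**
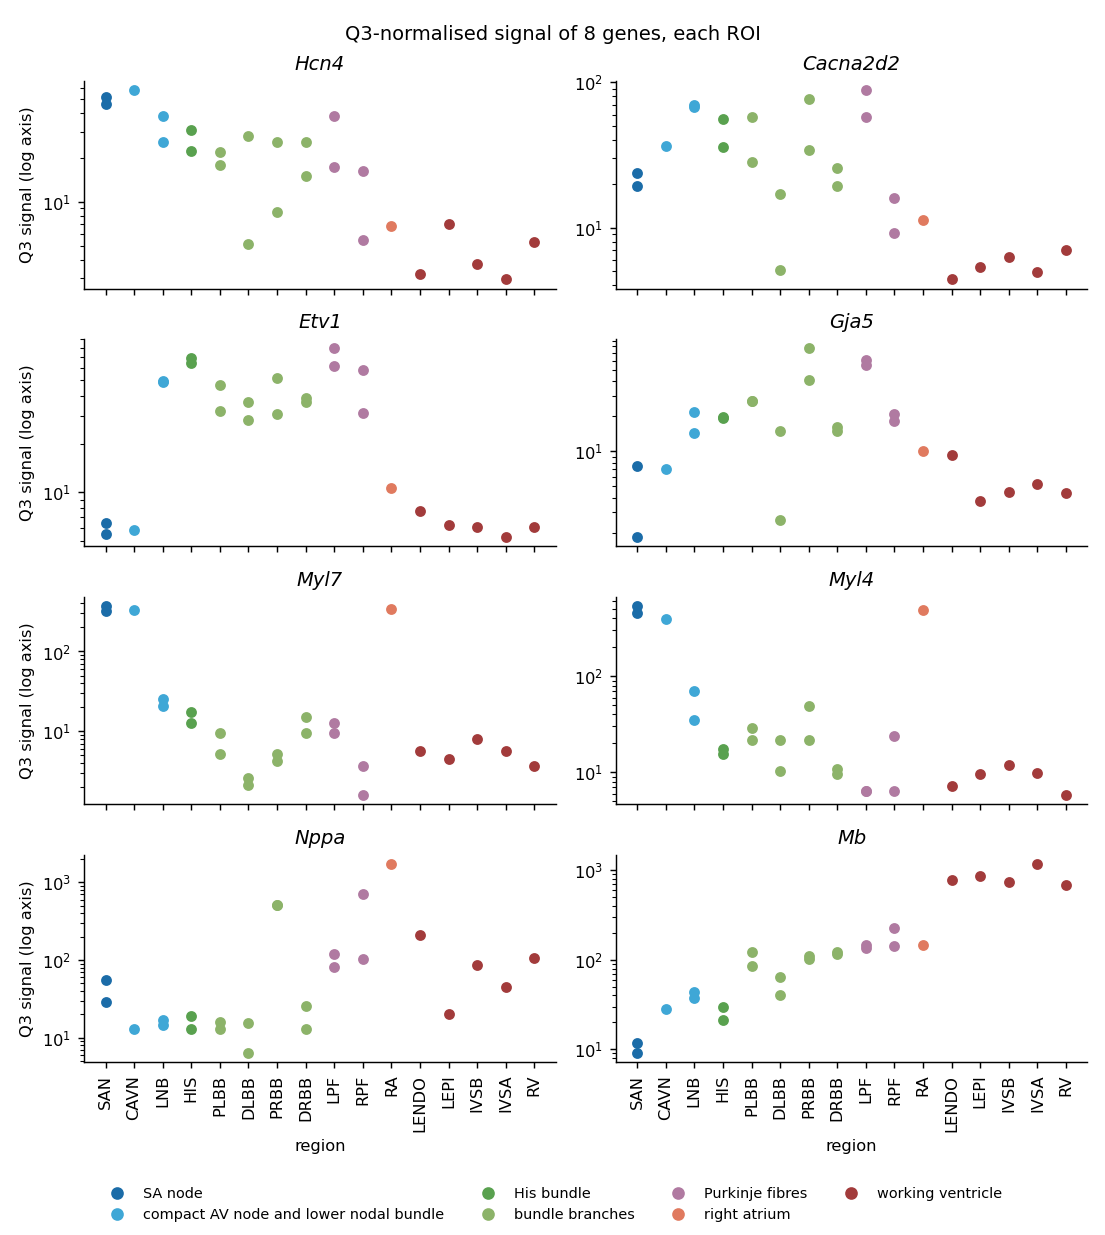
Q3 signal (log axis, units) of 8 genes in every ROI, with each ROI a point and regions along the horizontal axis. Hcn4 and Cacna2d2 lie mostly higher in conduction than in working regions, with some overlap in DLBB and RPF, Myl7 and Myl4 are highest in SAN, CAVN and RA, and Mb lies above every conduction ROI in the 5 working ventricular ROIs.

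Among the fixed lists, 8 of 16 nodal pacemaker genes rose and none fell, or 10 adjusted over the list alone (camera adjusted p = 3.6e-30), with Hcn4, Cacna2d2, Igfbp5 and Cpne5 leading. Of 19 His-Purkinje genes 9 rose and none fell, against 11 and 1 adjusted over the list alone (camera 1.2e-24). Axon guidance and neural adhesion genes behaved likewise, with 8 of 15 higher and 1 lower, or 10 and 1 adjusted over the list alone (camera 4e-20). The axon guidance list is not separate from the other lists in any comparison. It shares Cntn2, Slit2, Sema3a and Ephb3 with the His-Purkinje list and Ntm with the nodal list. The guidance receptor Robo1 (34.2 ± 22.5 against 7.18 ± 1.19, log2 change 1.81 ± 0.31, limma adjusted p = 0.000145) and the Eph receptor Ephb3 (1.24 ± 0.22, adjusted p = 0.000225) were in that group, while the ligand gene Efnb3 fell (−1.48 ± 0.24). These 3 lists kept their calls with an estimated correlation. The cardiac transcription factor list was higher by camera (adjusted p = 0.000359, against adjusted p = 0.06 with an estimated correlation), although 2 of its 20 genes rose and 3 fell (4 and 3 adjusted over the list alone), among them Gata6 (−1.17 ± 0.28).

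Genes of energy metabolism fell against the working ventricle, whereas the lone RA ROI read 15.4 for Uqcrc1, 13.9 for Hadhb and 41.6 for Fabp3, no higher than the conduction means (16.3, 15.95 and 76.7). Of 38 oxidative phosphorylation genes 35 were lower and none higher (38 adjusted over the list alone; camera adjusted p = 3.6e-30, adjusted p = 0.073 with an estimated correlation). Uqcrc1, a subunit of respiratory complex III, read 16.3 ± 4.13 against 54.9 ± 23.9 (log2 change −1.56 ± 0.24, limma adjusted p = 3.7e-05), and Cox7a1, a muscle subunit of cytochrome c oxidase, changed by −1.43 ± 0.25 (adjusted p = 0.000201). Fatty acid oxidation followed, with 19 of 21 genes lower by either adjustment, 19 adjusted over the list alone (camera 2.0e-21, and 0.0393 with an estimated correlation). Hadhb, of the mitochondrial trifunctional protein, fell to 15.95 from 61.4 (log2 change −1.79 ± 0.27, adjusted p = 3.1e-05). The fatty acid binding protein genes Fabp3 (−2.37 ± 0.40, adjusted p = 0.000147) and Fabp4 (−2.74 ± 0.30, 6.9e-08), the latter a member of the endothelial list, fell as well. Glycolysis genes were lower in 7 of 19 cases (10 adjusted over the list alone; camera 0.00215, adjusted p = 0.27 with an estimated correlation), a call that ended under quantile normalization (0.438).

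Contractile and growth genes were lower in part. Of 13 working ventricular genes 7 fell and 1 rose, by either adjustment and so also adjusted over the list alone (camera 1.2e-05, adjusted p = 0.073 with an estimated correlation). Gja1, the main connexin of working muscle (24.1 against 73.4, log2 change −2.14 ± 0.39, adjusted p = 0.000365), and Fhl2 (−1.88 ± 0.26) were among them. Of 22 sarcomere genes 9 fell (12 adjusted over the list alone), such as Actn2 (−1.25 ± 0.25); the list test gave 8.8e-06, adjusted p = 0.27 with an estimated correlation, and 0.0986 under quantile normalization. Calcium handling genes were lower in 4 of 16 cases, or 7 adjusted over the list alone (camera 0.0185, adjusted p = 0.397 with an estimated correlation, 0.179 under quantile normalization), and Ryr2, the release channel of the sarcoplasmic reticulum, changed by −1.13 ± 0.23. Of 20 cell cycle genes 7 fell (12 adjusted over the list alone; camera 1e-04, adjusted p = 0.0975 with an estimated correlation), among them Cdc20 (−1.06 ± 0.22, adjusted p = 0.00098) and Rrm2 (−1.05 ± 0.21). With working myocardium thinned to conduction depth neither gene was called (Cdc20 −0.83, Rrm2 −0.73).

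Markers of other cell types moved apart, which the metabolic lists are read beside. Endothelial genes fell in 7 of 15 cases (11 adjusted over the list alone; camera 9.8e-08), with the junction gene Cdh5 at 11.7 against 36.5 (log2 change −1.55 ± 0.21, adjusted p = 4.9e-06). Of 14 fibroblast genes none was called by limma, nor adjusted over the list alone, yet the list lay above other genes (camera 1.9e-06, adjusted p = 0.067 with an estimated correlation), with Col1a1 at 0.83 (adjusted p = 0.0653). After thinning 2 of them were called higher, and under quantile normalization 4. The extracellular matrix list was higher (camera 0.00402, adjusted p = 0.27 with an estimated correlation, 0.0635 after thinning), with 1 of 22 genes up and 2 down, or 2 and 2 adjusted over the list alone, a median of 0.03 and a mean just below 0; Eln, which encodes elastin, rose by 1.37 ± 0.30 (adjusted p = 0.00206). Working atrial genes were higher by camera (0.000415, adjusted p = 0.238 with an estimated correlation) with 1 of 10 called, also adjusted over the list alone, and the call ended under quantile normalization (0.0967). Connexins gave 0.0418 (adjusted p = 0.261 with an estimated correlation) with 1 higher and 1 lower of 4 by either adjustment, so also adjusted over the list alone, and a median (0.26) and mean (−0.05) of opposite sign. Lists of sodium and potassium channels (camera 0.145), endocardial (0.11), mural (0.559), macrophage (0.759), epicardial (0.759), neural and glial (0.107) and immediate early genes (0.453) were not called. Of the lists with under 3 tested members, the hemoglobin genes Hba-a1 (−1.37, adjusted p = 0.198) and Hbb-b1 (−1.19, 0.234) and the Y-linked Uty (−0.18, 0.613) were not called.

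In all, limma called 698 of 7848 targets, 63 higher, 3 of them transgene targets, and 635 lower. By fry, which asks whether a list's genes move on balance in 1 direction, oxidative phosphorylation (adjusted p = 0.00269) and fatty acid oxidation (0.000826) were lower and the nodal list (0.00103) was higher, while fibroblast (0.351) and working atrial genes (0.731) did not pass. The groups did not overlap for 56 of the called targets. Chance gives 0.0250% of all targets for 10 against 6 regions, a share that cannot be set against targets already chosen for their difference. The median target lay at −0.23 on the log2 scale, and 9.03% of calls were higher. After thinning of working myocardium the median was −0.02 and limma called 97 higher and 209 lower (31.7% higher). Quantile normalization gave 381 and 387 (49.6%). EdgeR gave 269 and 500 (35.0%), but it left out RA, LEPI, IVSB and RV. Its working group was LENDO and IVSA alone, so its counts cover fewer samples. As list median minus the median of all genes, oxidative phosphorylation lay at −0.87 (−0.90 thinned and −0.57 quantile normalized), fatty acid oxidation at −1.12 (−1.08 and −0.95) and endothelial genes at −0.44 (−0.43 and −0.56), while nodal genes lay at 1.05 (1.204 and 1.36), His-Purkinje genes at 1.16 (1.00 and 1.30) and fibroblast genes at 0.50 (0.43 and 0.54). Without IVSA the count was 355, without LEPI 418 and without LENDO 438. Working regions had 1 ROI each, and ROIs may share an animal.

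**Figure D3:**
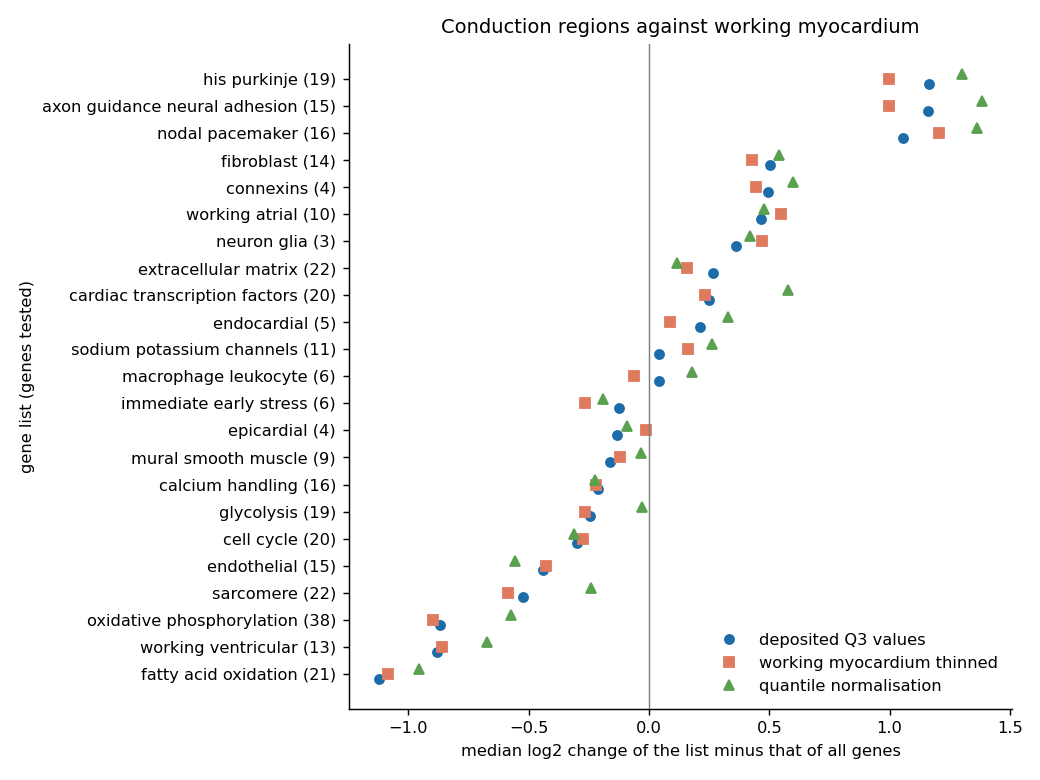
Median log2 change of each gene list minus the median of all genes, conduction against working regions, for the deposited Q3 values, with working myocardium thinned and after quantile normalization. Oxidative phosphorylation lies at −0.87, −0.90 and −0.57 and nodal genes at 1.05, 1.204 and 1.36, so both keep their side under the 3 scalings.

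Restriction to the ventricle, 7 conduction against 5 working regions, removed the difference between chambers. Of the genes named by the rule, transgene targets aside, Etv1 rose most, from 6.26 ± 0.856 to 46.7 ± 15.0 (6.37-fold, log2 change 2.67 ± 0.22, limma adjusted p = 4.3e-12). Gja5 rose by 1.98 ± 0.32 (29.0 ± 20.3 against 5.41 ± 2.21, adjusted p = 2.0e-05), Hcn4 by 1.80 ± 0.25 (18.3 ± 6.40 against 4.46 ± 1.72, 1.9e-06), Cntn2 by 1.60 ± 0.28 (7.9e-05) and Irx3 by 1.19 ± 0.23 (0.000257). Fabp4 fell to 11.4 from 106 (log2 change −3.29 ± 0.26, adjusted p = 4.3e-12), Mb to 104 from 853 (−3.22 ± 0.32, 1.0e-09) and Hadhb to 17.0 ± 9.59 from 70.9 ± 13.9 (−2.10 ± 0.24, 3.4e-08). Nppa (−0.53, adjusted p = 0.583), Tbx3 (−0.30, 0.519) and Shox2 (−0.05, 0.928) were not called. Myl2, the ventricular regulatory light chain, changed by −1.06 ± 0.33 (0.0323), a call that ended with thinned working myocardium (−0.92). In edgeR, with LENDO and IVSA as the only working ROIs, Myl2 was at −0.999 and not called.

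By list, 10 of 19 His-Purkinje genes rose (13 adjusted over the list alone; camera 1.8e-30) and 8 of 16 nodal genes (8 adjusted over the list alone; 4.6e-23). Of 15 axon guidance and adhesion genes 9 rose and 1 fell, in both the all-gene count and the count adjusted over the list alone (4.6e-23); Ncam1 changed by 1.37 ± 0.22. Oxidative phosphorylation genes were lower in 37 of 38 cases (38 adjusted over the list alone; 4.5e-34), led by Uqcrc1 (−1.77 ± 0.21), and fatty acid oxidation genes in 19 of 21 (19 adjusted over the list alone; 4.4e-26). Endothelial genes fell in 7 of 15 (12 adjusted over the list alone; 2.1e-07), as did Kdr (−1.64). Of 14 fibroblast genes 5 rose, and 5 adjusted over the list alone (camera 4.4e-08), with Col1a1 at 1.01 ± 0.28 (0.0116). In edgeR, against LENDO and IVSA alone, Col1a1 was at 0.67 and not called. Working ventricular genes fell in 9 of 13 cases with 1 higher, the same numbers as adjusted over the list alone (camera 3.2e-08), and working atrial genes rose in 2 of 10 (3 adjusted over the list alone; 4.9e-08). These 9 lists kept their calls with an estimated correlation. Others did not: sarcomere genes (0 higher and 13 lower of 22, camera 3.7e-07, adjusted p = 0.183 with an estimated correlation), glycolysis (0 and 9 of 19, 0.000347, adjusted p = 0.154 with an estimated correlation), cell cycle (0 and 7 of 20, 5.4e-05, adjusted p = 0.077 with an estimated correlation), calcium handling (0 and 6 of 16, 0.025, adjusted p = 0.413 with an estimated correlation) and extracellular matrix (4 and 3 of 22, 0.000211, adjusted p = 0.239 with an estimated correlation). Adjusted over the list alone, 17 sarcomere, 11 glycolysis, 13 cell cycle and 7 calcium handling genes were lower, and 5 matrix genes were higher and 3 lower.

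Limma called 821 targets in the ventricle, 92 higher and 729 lower, with a median of −0.27 and 11.2% of calls higher. After thinning the median was −0.05 and 111 were higher and 277 lower (28.6%). Quantile normalization gave 480 and 518 (48.1%). EdgeR, with LENDO and IVSA as the only working ROIs, gave 246 and 386 (38.9%). Relative to the median of all genes, oxidative phosphorylation lay at −0.98 (−1.01 thinned, −0.66 quantile normalized) and His-Purkinje genes at 1.35 (1.21 and 1.37). Without IVSA 498 were called.

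Nodal regions (SAN, CAVN and LNB) were compared with the 7 His-Purkinje regions. The atrial light chain genes Myl7 (chromosome 11, 5896637 to 5898782, minus strand) and Myl4 (chromosome 11, 104550663 to 104595753, plus strand) were far higher on average in nodal regions. Myl7 read 234 ± 183 (SD, n = 3) against 7.84 ± 4.99 (SD, n = 7), a log2 change of 4.22 ± 0.40 (limma adjusted p = 2.3e-13), and Myl4 314 ± 235 against 16.9 ± 9.01 (3.75 ± 0.36, 2.3e-13). The ROIs of SAN and CAVN read 320 to 370 for Myl7, but those of LNB 25.7 and 20.6. For Myl4 LNB read 70.7 and 34.7, so both rises rest mainly on SAN and CAVN. Hcn4 rose by 1.31 ± 0.29 (45.8 ± 13.1 against 18.3 ± 6.40, adjusted p = 0.0077), and Bmp2, a morphogen of the atrioventricular canal (chromosome 2, 133552159 to 133562885, plus strand), by 1.67 ± 0.35 (0.00317). Myl2 (chromosome 5, 122100951 to 122113472, plus strand) was lower, 189 ± 261 against 845 ± 250 (−3.34 ± 0.48, 1.2e-06), as were Myl3 (−2.56 ± 0.39, 5.8e-06), Pln (−1.86 ± 0.33, 0.000135), Ncam1 (−1.58 ± 0.28, 0.000135) and Etv1 (−1.78 ± 0.33, 0.000314). Etv1 read 49.8 and 48.9 in LNB and 5.51 to 6.43 in SAN and CAVN, so its fall rests on SAN and CAVN. Gja5 (−1.43 ± 0.35, 0.0283) and Gja1 (−1.72 ± 0.38, 0.00774) were called lower, but neither was without both PRBB ROIs (−1.22 and −1.47).

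Of 16 nodal pacemaker genes 3 rose (7 adjusted over the list alone; camera 6.8e-07). Working ventricular genes fell in 6 of 13 cases (6 adjusted over the list alone; camera 3.5e-07), and connexins in 2 of 4 (3 adjusted over the list alone; 3.3e-05); these 3 lists kept their calls with an estimated correlation. His-Purkinje genes fell in 3 of 19 cases with 1 higher, or 10 and 2 adjusted over the list alone (6.8e-07, adjusted p = 0.168 with an estimated correlation). Oxidative phosphorylation genes were lower as a list although none passed alone (2 adjusted over the list alone; 2.3e-13, adjusted p = 0.17 with an estimated correlation). Sarcomere genes fell in 3 of 22 cases (3 adjusted over the list alone; 1.9e-09, adjusted p = 0.168 with an estimated correlation, 0.323 under quantile normalization). Fibroblast genes lay lower as a list (4.3e-05, adjusted p = 0.168 with an estimated correlation) with none called and 4 adjusted over the list alone, and the hemoglobin gene Hba-a1 was lower as well (−2.66 ± 0.50, adjusted p = 0.000497; not called without CAVN, −2.31). Tbx3 (1.06 ± 0.36, 0.287), Shox2 (0.92 ± 0.35, 0.331), Cntn2 (−0.29, 0.779), Irx3 (−1.02, 0.184) and Nppa (−1.24 ± 0.50, 0.384) were not called. In total 10 targets were higher and 25 lower. Without CAVN 11 were called, where Hcn4 (1.13), Bmp2 (1.28) and Etv1 (−1.30) no longer passed, and without DLBB ROI 2 18 were called. With single ROIs as units the count was 182 and without LNB it was 58.

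The next 6 comparisons rest on ROIs, which may come from 1 animal, so their p-values may be too small. Within the nodes, the sinoatrial node (2 ROIs) was compared with the atrioventricular junction, which is the mean of CAVN (1 ROI) and LNB (2 ROIs). Ankrd1, a stretch-responsive cofactor (chromosome 19, 36111961 to 36120099, minus strand), read 296 ± 74.8 against 57.3 ± 34.5 (log2 change 2.25 ± 0.25, limma adjusted p = 1.7e-12), and Myl4 rose by 1.81 ± 0.41 (0.013; not called without SAN ROI 1, 1.92, SAN ROI 2, 1.70, or LNB ROI 2, 1.56). For Myl4 the junction was not uniform, with 396 in CAVN, near the SAN ROIs (459 and 537), and 70.7 and 34.7 in LNB. Myl2 was lower, 17.5 ± 11.7 against 348 ± 249 (−3.43 ± 0.17, 1.8e-41), with Myl3 (−3.03 ± 0.20, 1.2e-29), Pln (−1.46 ± 0.23, 5.3e-06), Mb (−1.60 ± 0.25, 4.0e-06) and Myh7 (−1.82 ± 0.33, 0.000144). The SD of 249 shows that the junction was not uniform for Myl2 either. Etv1 read 5.85 in CAVN, near the SAN ROIs (5.51 and 6.43), and 49.8 and 48.9 in LNB. Differences of Myl2 and Etv1 from the SAN may thus rest mainly on LNB. Robo1 was also lower, at 7.43 against 55.6 (−2.09 ± 0.45, 0.0047), but not called without either SAN ROI (−2.08 and −2.10) or without LNB ROI 2 (−1.92). Hcn4 did not differ detectably at this depth, with 48.8 ± 3.79 against 40.5 ± 15.9 (0.19 ± 0.51). Shox2 stood at 30.3 against 10.7 without passing (1.37 ± 0.61). Nor were Tbx3 (0.64), Cntn2 (−1.06), Gja5 (−1.32), Etv1 (−1.42) or Irx3 (−1.59) called, while Nppa was (1.44 ± 0.36, 0.0428), though not without SAN ROI 1 (0.98) or CAVN (1.31).

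Working atrial genes rose in 2 of 10 cases (5 adjusted over the list alone; camera 4.1e-07), and working ventricular genes fell in 4 of 13 with 1 higher (4 and 1 adjusted over the list alone; 4.7e-05). His-Purkinje genes (0.00198) and cardiac transcription factors (0.00125) lay lower as lists, with 2 higher and none lower of 19, and none called of 20; adjusted over the list alone, 2 His-Purkinje genes were higher and 5 lower, and 2 transcription factor genes were lower. These 4 kept their calls with an estimated correlation. Sarcomere genes fell in 4 of 22 (5 lower and 1 higher adjusted over the list alone; 0.00125, adjusted p = 0.103 with an estimated correlation), and the nodal list was not called (0.355). Limma called 4 targets higher and 12 lower; quantile normalization gave 19 and 28 (40.4%) and edgeR 23 and 18 (56.1%). Without SAN ROI 1 the count was 6, without LNB ROI 2 it was 9 and without CAVN 32.

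The His bundle (2 ROIs) was compared with the bundle branches (8 ROIs), and every call was lower. Col3a1, a fibrillar collagen, read 63.8 ± 13.9 against 207 ± 68.1 (log2 change −1.62 ± 0.20, limma adjusted p = 1.3e-09), and Fbn1 (−1.87 ± 0.35, 0.00024; not called without HIS ROI 1, −1.28) and Dpt (−1.62 ± 0.34, 0.00306; not called without HIS ROI 2, −1.33) were lower too. Mb fell to 25.3 from 95.5 (−1.81 ± 0.21, 8.3e-11), and the fatty acid binding protein gene Fabp5 (chromosome 3, 10012548 to 10016607, plus strand) to 4.38, a level near the negative probe, from 32.6 ± 14.7 (−2.59 ± 0.38, 2.0e-07). Of 14 fibroblast genes 5 fell (6 adjusted over the list alone; camera 1.3e-08), of 22 matrix genes 2 (5 adjusted over the list alone; 5.3e-08), and of 13 working ventricular genes 1 (4 adjusted over the list alone; 7.6e-05), and these 3 calls held with an estimated correlation. Oxidative phosphorylation lay lower (7.3e-06, adjusted p = 0.176 with an estimated correlation, 0.864 under quantile normalization) with no gene called. Sarcomere genes lay lower too (0.000504, adjusted p = 0.105 with an estimated correlation, 0.864 under quantile normalization), and Actc1 among them was called (−0.65 ± 0.12, limma adjusted p = 0.00016). The nodal (0.491) and His-Purkinje (0.623) lists were not called. Pcp4, a calmodulin regulator, stood at 55.2 against 27.9 (1.27 ± 0.45, 0.521). Etv1 (0.84), Hcn4 (0.65), Cntn2 (0.44), Shox2 (0.44), Tbx3 (0.32), Irx3 (−0.03), Gja5 (−0.04), Myl2 (−0.27) and Nppa (−1.10) were not called. Hba-a1 was lower by limma (−2.0003 ± 0.25, 1.3e-09), but not without both PRBB ROIs (−0.70). No target was higher in limma and 16 were lower, with 382 at an unadjusted p under 0.05; edgeR gave 6 higher and 30 lower, and quantile normalization 6 and 15 (28.6% higher). The median of all genes was 0.12. Without HIS ROI 1 the count was 8, and without both PRBB ROIs it was 7.

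Purkinje fibers (4 ROIs) were compared with bundle branches (8 ROIs). Actc1, cardiac actin (chromosome 2, 114047282 to 114053548, minus strand), rose in Purkinje fibers by 0.96 ± 0.09 on the log2 scale (limma adjusted p = 4.0e-16), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.97 ± 0.15 (2.6e-06). Gja1 read 62.1 against 25.1 (1.63 ± 0.29, 5.7e-05), and Nppa, a natriuretic peptide gene (chromosome 4, 148000722 to 148002079, plus strand), 253 ± 302 against 139 ± 230 (2.19 ± 0.23, 1.6e-13; 1.51 without RPF ROI 2, which read 705 against 81.4 to 119 in the other Purkinje ROIs). The transcription factor genes Irx1 (1.58 ± 0.35, 0.00391) and Irx2 (1.58 ± 0.38, 0.0112) rose as well. Under quantile normalization Mb (0.49), Myh6 (0.25) and Myl2 (−0.04) were not called, against 0.82 ± 0.16, 0.89 ± 0.10 and 0.67 ± 0.11 in the deposited scaling. Lower in Purkinje fibers were Robo1 (17.99 against 40.4, −1.21 ± 0.29, 0.0106; not called without RPF ROI 2, −0.66), Col4a4 (−1.69 ± 0.36, 0.00268) and Col1a1 (−0.73 ± 0.16, 0.00426). Without RPF ROI 1 Irx1 (1.36), Irx2 (1.60), Col4a4 (−1.44) and Col1a1 (−0.55) were not called. Gja5 (0.72), Cntn2 (0.56), Etv1 (0.55), Irx3 (0.27), Tbx3 (0.22), Hcn4 (−0.05) and Shox2 (−0.67) were not called.

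Of 22 sarcomere genes 6 rose and none fell (12 adjusted over the list alone; camera 3.4e-05, adjusted p = 0.055 with an estimated correlation, 0.286 under quantile normalization). Working ventricular genes rose in 5 of 13 cases (7 adjusted over the list alone; 0.00122, adjusted p = 0.055 with an estimated correlation), calcium handling genes in 3 of 16 (8 adjusted over the list alone; 0.000798, adjusted p = 0.059 with an estimated correlation) and His-Purkinje genes in 4 of 19 with 1 lower (5 and 3 adjusted over the list alone; 0.00677, adjusted p = 0.055 with an estimated correlation). Oxidative phosphorylation genes rose in 3 of 38 (12 adjusted over the list alone; 4.1e-05, adjusted p = 0.156 with an estimated correlation, 0.305 under quantile normalization). Limma called 58 higher and 20 lower (74.4% higher), quantile normalization 15 and 12 (55.6%), and edgeR 62 and 10. Without RPF ROI 2 the count was 21, without LPF ROI 2 it was 29, without LPF ROI 1 it was 44, and without both PRBB ROIs it was 268.

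The left side of the ventricular conduction system (PLBB, DLBB and LPF, 6 ROIs) was compared with the right (PRBB, DRBB and RPF, 6 ROIs). Nppa was lower on the left, 41.9 ± 46.8 against 312 ± 300 (log2 change −2.44 ± 0.22, limma adjusted p = 2.9e-18; −1.50 without both PRBB ROIs and −1.98 without RPF ROI 2), and Ankrd1 was lower too (−0.93 ± 0.15, 1.4e-05; not called under quantile normalization, −0.54). The fall of Ankrd1 came from Purkinje fibers (−3.39), while bundle branches stood at 0.29. Eln (chromosome 5, 134702593 to 134747323, minus strand) was the only target higher on the left, 117 ± 46.7 against 58.3 ± 6.22 (0.91 ± 0.19, 0.00246), though not called without PLBB ROI 1 (0.71). Hemoglobin targets were lower on the left, with Hba-a1 (chromosome 11, 32283511 to 32284465, plus strand) at −2.68 ± 0.19 (6.4e-27), and hemoglobin took 3.41 and 2.58% of the counts of the PRBB ROIs. Gja1 (−1.29 ± 0.27, 0.00285) was not called without both PRBB ROIs (−0.99), and Actc1 (−0.58 ± 0.09, 5.1e-07) was not called under quantile normalization (0.09). The 9 genes tested in every comparison were otherwise not called, as Hcn4 (0.36), Irx3 (0.32), Tbx3 (0.24), Etv1 (0.15), Cntn2 (0.12), Shox2 (−0.18), Gja5 (−0.21) and Myl2 (−0.29) show. The nodal list lay higher on the left with none of 16 called (camera 0.026, adjusted p = 0.182 with an estimated correlation). Working ventricular genes lay lower, with 2 of 13 called (6 adjusted over the list alone; 0.00724, adjusted p = 0.102 with an estimated correlation, 0.182 under quantile normalization). Limma called 1 higher and 17 lower (5.56% higher), quantile normalization 5 and 6 (45.5%), and edgeR 1 and 15. Without RPF ROI 2 the count was 9.

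Proximal bundle branches (PLBB and PRBB, 4 ROIs) were compared with distal ones (DLBB and DRBB, 4 ROIs). In the deposited scaling Gja5 had 43.2 ± 23.6 against 12.2 ± 6.41 (log2 change 1.85 ± 0.39, limma adjusted p = 0.00294), Cntn2 29.2 ± 11.1 against 8.52 ± 5.37 (1.74 ± 0.40, 0.00828) and Cacna2d2 a change of 1.57 ± 0.33 on the log2 scale (0.00294). Kcne1, a potassium channel subunit, was lower, 22.5 against 50.6 (−1.25 ± 0.31, 0.0166). Nppa read 263 ± 287 against 15.1 ± 8.02 (2.61 ± 0.27, 3.1e-14), but without both PRBB ROIs its change was 0.08. The hemoglobin gene Hba-a1 likewise went from 2.24 ± 0.23 to −0.54. Without the PRBB ROIs Gja5 (1.33), Cntn2 (1.72), Cacna2d2 (1.41) and Kcne1 (−0.52) kept their sign and were not called. Slit2 (1.67 ± 0.41, 0.0165) was not called in edgeR (1.56) or under quantile normalization (1.36). Hcn4 (0.13), Tbx3 (0.43), Irx3 (−0.40), Etv1 (0.17), Shox2 (0.61) and Myl2 (0.23) were not called. Of 19 His-Purkinje genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; camera 0.014, adjusted p = 0.108 with an estimated correlation), and of 15 axon guidance genes 2 rose (2 adjusted over the list alone; 0.014, adjusted p = 0.208 with an estimated correlation).

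Limma called 76 targets higher proximally and 4 lower, with the median of all genes at 0.20. Quantile normalization gave 11 and 10 (52.4%), 15 of them shared with the deposited scaling, and edgeR gave 12 and 3. Relative to the median of all genes, the His-Purkinje list lay at 0.52 (0.49 under quantile normalization). On the left side alone 7 targets were called between PLBB and DLBB, all higher, and on the right 31 between PRBB and DRBB, with 26 higher and 5 lower. The count was 21 without PLBB ROI 1, 22 without PLBB ROI 2, 25 without PRBB ROI 1, 42 without PRBB ROI 2, 43 without DLBB ROI 1, 44 without DRBB ROI 1 and 4 without both PRBB ROIs.

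The sinoatrial node (2 ROIs) was also set against the right atrial appendage (1 ROI). Variation between RA samples was not measured: limma took its spread from the conduction regions with 2 ROIs, which differed by about counting error (chi-square per degree of freedom 0.78 to 1.05). Its calls therefore describe these ROIs only, and the values of single genes are given without p-values. Lower in the node were, as log2 changes, −5.40 for Nppa, −3.71 for Mb (10.5 against 148), −3.61 for Nppb, −2.97 for Gja1, −2.68 for Igf2 and −1.41 for Myl3. Bmp10, an atrial growth factor gene (chromosome 6, 87428994 to 87437677, plus strand), stood at −3.46, and at −3.27 and −3.65 without either SAN ROI. Hcn4 read 48.8 ± 3.79 against 6.79 (2.67). Changes were smaller for Shox2 (1.28), Tbx3 (1.17), Myl2 (0.20), Cntn2 (0.10), Irx3 (−0.24), Etv1 (−0.75) and Gja5 (−1.16). As a list, nodal pacemaker genes lay at 1.06 above the median of all genes (1.205 thinned, 1.33 quantile normalized), and working atrial genes at 0.50 below it (0.52 and 0.65). Limma called 7 lower and 1 higher, the tdTomato target, so 12.5% of calls were higher; quantile normalization gave 4 and 9 (30.8%) and thinning 5 and 7. The median of all genes was −0.14. In simulated counts this comparison recovered none of 53 changes of 2-fold and 8.62% of 58 changes of 4-fold, so genes not called are not shown to be equal.

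The single-cell library held 98518660 UMIs over 31055 genes, with a median of 13331 UMIs and 3312 genes per cell and between 4435 and 39054 UMIs. The percent of UMIs from mitochondrial genes ran from 5.00 to 24.96%. Shares below describe cells that passed a tdTomato gate set at 0.1 to 0.2% of viable cells and the authors' filters, not the heart. Purkinje fiber cells made up 5203 of 6855 cells, or 75.9% (95% interval 74.9 to 76.9). Bundle branch cells made up 11.7% (10.98 to 12.5), His bundle cells 6.49% (5.92 to 7.10), proliferative cells 3.24% (2.83 to 3.69) and contractile cells 2.01% (1.69 to 2.37). Nodal cells were rare, with 26 atrioventricular node cells (0.379%, 0.248 to 0.555) and 17 sinoatrial node cells (0.248%, 0.1445 to 0.397). The cell types are the authors' labels, and median depth ran from 10407 UMIs in atrioventricular node cells to 17758 in proliferative cells.

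**Figure D4:**
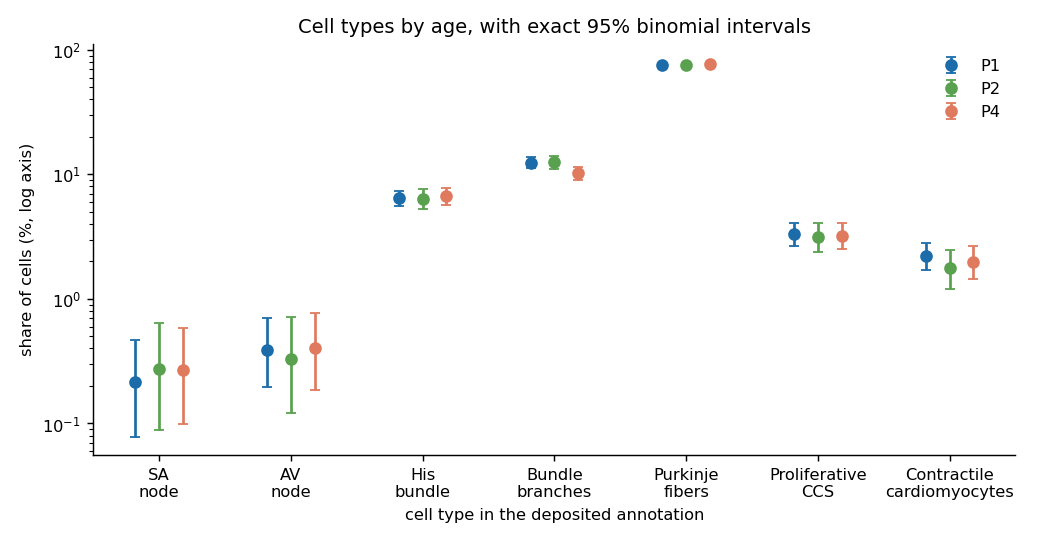
Share of cells (percent, log axis) of each cell type at P1, P2 and P4, with exact 95% binomial intervals that cover counting error only. Purkinje fiber cells make up 75.04, 75.6 and 77.2% of cells at the 3 ages, and bundle branch cells 12.4, 12.5 and 10.2%.

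Cell types differed in the genes that name them. Hcn4 reached 146 CPM in sinoatrial cells, 65.6 in atrioventricular cells, 57.5 in His bundle cells, 33.2 in bundle branch cells and 38.4 in Purkinje cells, against 5.01 in contractile cells. Shox2 stood at 301 CPM in sinoatrial and 89.5 in atrioventricular cells, against 0.16 in His bundle and 0.03 in Purkinje cells. Tbx3 stood at 83.5 and 80.5 CPM in the nodes and at 47.0, 12.9 and 7.87 in His bundle, bundle branch and Purkinje cells. Gja5 ran the other way, at 16.7 and 8.95 in the nodes, 90.6 in His bundle, 137 in bundle branch and 122 in Purkinje cells, and Etv1 stood at 50.1, 89.5, 272, 240 and 315 in the same order. Cntn2 was between 20.9 (atrioventricular) and 82.7 CPM (Purkinje) in conduction cells and 7.10 in contractile cells. Irx3 was also high in Purkinje cells (126), against 37.6 in sinoatrial cells, and Isl1 had 0.07 CPM in Purkinje cells and no UMI in the other types. Myl2 was abundant outside the nodes, at 9833 CPM in Purkinje and 12231 in contractile cells, against 1061 in sinoatrial cells.

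Among the genes of highest fold, Sln, Myl7, Myl4 and Shox2 led in sinoatrial cells, and Rspo3, a Wnt signalling enhancer, reached 704 CPM in atrioventricular cells. His bundle cells were marked by Lyz2, Pcp4 (248 CPM against 11.6 in bundle branch and 41.2 in Purkinje cells) and Robo1 (69.6 CPM against 19.3 and 22.9). Bundle branch cells were marked by Nppa, at 9368 CPM against 1167 in the other conduction types together, Gal and Sfrp5, and Purkinje cells by Psd3, Ucp2 and Mb (922 against 506). Summed over the cell cycle list, proliferative cells had 4324 CPM against 53.8 to 267 in the other types. Contractile cells had 80335 CPM of oxidative phosphorylation genes against 47627 to 55597 in the others, and 388 CPM of axon guidance genes against 1044 to 1699 in the conduction types. The macrophage list summed to 326 CPM in His bundle, 215 in bundle branch and 214 in proliferative cells, against 8.35 to 38.8 elsewhere. Lyz2 alone gave nearly all of it in His bundle (323 CPM) and bundle branch cells (212), so these sums do not show a macrophage signature. Endothelial genes stayed at 13.8 to 58.5 CPM. Free RNA in droplets adds UMIs to every cell, and low levels of abundant genes of other types cannot be read as expression.

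Ages differed little. The share of Purkinje cells was 75.04, 75.6 and 77.2% at P1, P2 and P4, and that of bundle branch cells 12.4 (11.2 to 13.7), 12.5 and 10.2% (8.96 to 11.5). Proliferative cells made up 3.31, 3.14 and 3.23%. Of 2608 genes considered over 6495 conduction cells, 2 had a fold of at least 2 between P1 and P4. Gal, a neuropeptide gene (chromosome 19, 3409915 to 3414544, minus strand), stood at 50.6, 49.6 and 23.6 CPM, a ratio of P4 to P1 of 0.466 (0.427 to 0.508). The hemoglobin gene Hbb-bs (chromosome 7, 103826534 to 103828096, minus strand) stood at 77.2, 52.8 and 29.8 CPM (ratio 0.387, 0.358 to 0.417), but the 5 cells with most Hbb-bs UMIs held 71.4, 73.5 and 52.5% of them, and the share of cells with any was 16.7, 18.1 and 18.9%, so this fall rests on few cells. For Gal the top 5 cells held 29.4, 45.9 and 34.4%. Nppa (−0.27), Cntn2 (0.12), Hcn4 (−0.02) and Myl2 (0.01) moved little as log2 ratios of P4 to P1. The median size of the log2 ratio over the genes was 0.0250 between P1 and P4, against 0.114 between His bundle and Purkinje cells.

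Markers of the single-cell types were then read in the ROIs, each component against the mean of the other conduction components. Genes that marked sinoatrial cells lay higher in the SAN ROIs (median log2 change 0.66, camera adjusted p = 1.0e-12), with 5 of 35 called, among them Myl4 (4.23), Myl7 (4.45) and Csrp2 (2.25). Genes of atrioventricular cells lay higher in the atrioventricular junction (0.46, 2.5e-05), with 3 of 41 called, Gata6 (1.63) among them. They were also called higher in the SAN ROIs (0.44, 2.8e-08), and sinoatrial genes in the junction (0.29, 0.0027), so atrioventricular markers were not specific to the junction. The sinoatrial and atrioventricular lists share many genes, and every member called higher in the SAN or the junction was on both. Their calls in the SAN and the junction are therefore not separate results. Purkinje cell genes lay higher in Purkinje ROIs (0.31, 6.4e-06), with 11 of 39 called, but so did bundle branch cell genes (0.23, 0.0064). Markers of His bundle cells in His ROIs (0.24, 0.215) and of bundle branch cells in bundle branch ROIs (−0.05, 0.933) were not called, the latter with a median below 0 and a camera direction upward. His bundle markers were called higher in bundle branch ROIs instead (0.08, 0.0054). Nppa, the bundle branch marker of highest fold, was not higher in bundle branch ROIs (log2 change −0.008, limma adjusted p = 0.993). It read 514 and 509 in the PRBB ROIs and 6.43 to 25.7 in the other bundle branch ROIs. The 7 calls named here held with an estimated correlation. With 20 markers per type the Purkinje (0.0873) and bundle branch calls (0.172) in Purkinje ROIs were lost.

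**Figure D5:**
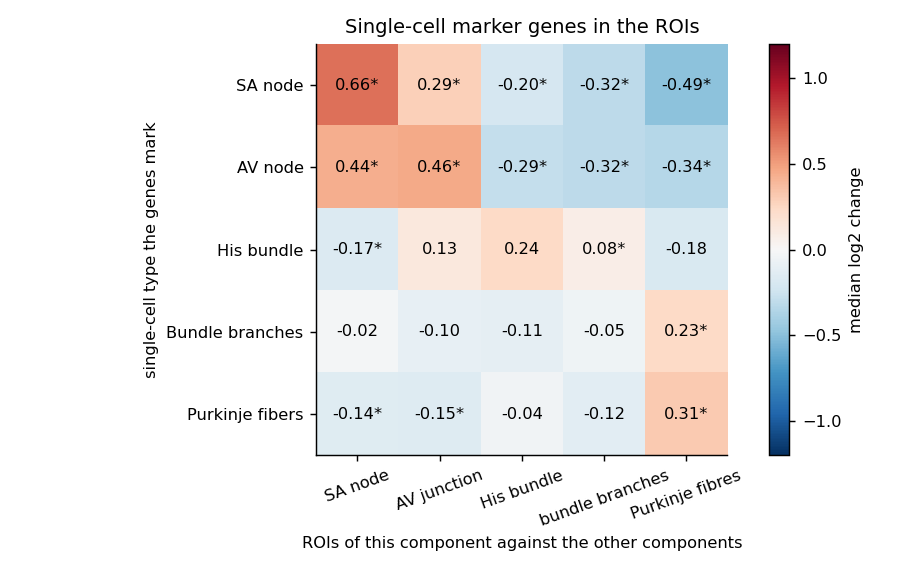
Median log2 change in each conduction component (columns) of the marker genes of each single-cell type (stacked from SA node to Purkinje fibers), relative to the other components, with an asterisk where the camera adjusted p was under the threshold of 0.05. Sinoatrial markers reach 0.66 in the SAN and atrioventricular markers 0.46 in the junction, and these lists share many genes.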

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

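The tests of explanations and the regroupings of samples in this part were chosen only after the results were seen. Within each group of 4 to 10 regions or ROIs, a value was singled out when its gap to the nearest other was large against the whole range. Of 494 groups 43 held such a value, and chance alone gives one in about 1 in 20 groups, or 24.7. Most belonged to the right atrial appendage, to the right Purkinje fibers or to the proximal right bundle branch.

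Among the 6 working regions RA, the single atrial one, stood apart in muscle and metabolic genes. Its signals were 13.4 for Myl2 (others 1386 to 2345), 148 for Mb (692 to 1178), 41.6 for Fabp3 (423 to 946), 32.3 for Fabp4 (85.9 to 127), 9.47 for Ankrd23 (48.2 to 55.2), 39.7 for Tnni1 (91.7 to 117), 66.3 for Mybpc3 (239 to 315) and 72.5 for Ryr2 (128 to 168). Lower values were also found there for Uqcrc1 at 15.4 (49.5 to 88.7), Acsl1 at 15.2 (29.8 to 42.2), Hadhb at 13.9 (53.6 to 91.0), Acadvl at 19.6 (58.5 to 86.7) and Eno3 at 67.3 (178 to 304), and a higher one for Stard10 at 38.4 (6.43 to 10.9). LEPI had a low Ephb3 of 4.98 among the working regions (7.52 to 8.44), whether or not RA was included. Among the 5 working ventricular regions Clu read 19.9 in IVSB (14.8 to 15.8) and Postn 126 in LENDO (39.7 to 49.8).

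Among the 10 conduction regions RPF was high in Nppb at 68.7 (5.85 to 11.6), Nmrk2 at 39.6 (3.39 to 9.15) and Ankrd23 at 30.4 (4.60 to 11.6), and low in Cpne5 at 7.69 (19.7 to 36.8). Nppb, Nmrk2 and Cpne5 stood apart among the 7 His-Purkinje regions too, where Tnni1 in RPF was 63.8 (36.9 to 44.8). CAVN had a Cox7a1 of 5.85 (15.8 to 26.0), PRBB a Hadhb of 38.2 (10.5 to 16.5) and DLBB an Acadvl of 9.15 (15.2 to 22.96), the last pair also among the His-Purkinje regions. Hemoglobin targets took 2.999% of the counts of PRBB, against 0.0294 to 0.770% in the other conduction regions.

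Single ROIs stood apart within components. Among the 4 Purkinje ROIs, RPF ROI 2 read 1.84 for Cdh6 (8.57 to 11.3), 23.9 for Myl4 (others 6.43) and 224 for Mb (137 to 148), RPF ROI 1 read 355 for Myl3 (414 to 424), and LPF ROI 2 read 3.21 for Tbx3 (6.43 to 7.35). Among the 8 bundle branch ROIs, Hmgn3 was 3.21 in DRBB ROI 1 (10.7 to 23.1), Cdh6 5.14 in PRBB ROI 2 (12.9 to 25.7) and Slc8a1 62.2 in DLBB ROI 2 (94.3 to 108). Among the 4 distal ROIs, Gja5 was 2.57 in DLBB ROI 1 (15.0 to 16.1) and Myl4 21.4 in DLBB ROI 2 (9.64 to 10.7).

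Effects also differed between parts of the heart by tests of the difference itself in limma. The proximal to distal change differed between left and right for 11 targets, 6 higher on the left and 5 lower, such as Nppa (left minus right −4.26 ± 0.54), Hbb-b1 (−4.23) and Hba-a1 (−4.16). Nppa changed by 0.48 on the left and 4.74 on the right, Ankrd1 by 1.67 and −0.30, and Tnnt2 by 0.30 and −1.09. The left to right difference was unlike in Purkinje fibers and bundle branches for 46 targets, 35 higher and 11 lower, such as Sbk2 (4.54), Cacna2d2 (3.20), Ankrd1 (−3.68 ± 0.33) and Ccn2 (−3.38). The model also set apart 15 targets, 8 higher and 7 lower, whose conduction to working difference was unlike in atrium and ventricle, but every working region had 1 ROI, so no spread of working myocardium entered and these calls describe these ROIs only. Nppa changed by −5.40 in the atrium and −0.53 in the ventricle, Etv1 by −0.75 and 2.67, and Fabp3 by −0.39 and −2.69. These tests rest on ROIs that may share an animal.

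In the single-cell library 476 cells (6.94%) held UMIs of both Xist and Y-linked genes, with a median of 18858.5 UMIs against 13397 in cells with UMIs of only Xist or only Y-linked genes. With at least 3 Xist and 2 Y-linked UMIs there were 109 cells (1.59%). Xist alone was seen in 47.9% of cells and Y-linked genes alone in 35.3%, so the pool held cells of both sexes.

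Conduction regions read lower than working myocardium at the median gene and, far more, in oxidative phosphorylation, where the lone RA ROI was near the node (Atp5b changed by −0.09 in the atrium and −1.31 in the ventricle). Deeper counting of working myocardium may account for the former, since thinning it to conduction depth moved the median log2 change from −0.23 to −0.0208. It does not account for the latter, because after thinning the list still lay at −0.90 against all genes and 26 of 38 members were called lower. Markers of other cell types cannot decide on a lower share of cardiomyocytes in conduction ROIs, since fewer cardiomyocytes need not raise every other type alike. After thinning endothelial genes lay at −0.43 against all genes (camera 1.7e-05, adjusted p = 0.011 with an estimated correlation). A like rise of all other types would not give this fall. Fibroblast genes lay at 0.43 (0.00035, adjusted p = 0.145 with an estimated correlation), which excludes nothing. A lower share of cardiomyocytes and changes in single other cell types stay open, as does the biological difference between conduction and working myocytes. With an estimated correlation the oxidative phosphorylation list itself did not pass (adjusted p = 0.073, median log2 change relative to all genes −0.87, with 35 of 38 members lower).

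Proximal bundle branches read higher than distal ones for 76 of 80 called genes. Coarse scaling of shallow ROIs cannot be told apart from a difference of the tissue. Under quantile normalization the median log2 change of the 76 genes went from 1.33 to 0.999, with a median SE of 0.310 and 0.319, and that of all genes from 0.20 to −0.01, so the 76 still lay 1.009 above all genes. The smaller changes against a like SE ended all but 11 of these calls, while 75 of the 76 kept their sign, so neither the lost calls nor the remaining change decides. A difference of the right branch alone cannot be told apart from one of both sides: genes chosen on the right exceeded all genes on the left by 0.0350 on the log2 scale, within the range of random sets (up to 0.317), genes chosen on the left exceeded all genes on the right by 0.119 (random sets up to 0.294), and 1 pair of regions per side keeps it open. A biological gradient along the branches stays open and was not tested apart from these.

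Summed expression of conduction cells was nearly equal at P1 and P4. Mixed age labels cannot be excluded or shown: the median size of the log2 ratio was 0.0329 between part of the P1 cells and as many P4 cells, and 0.0305 between parts of the P1 cells. Free RNA shared by the pooled library would act in the same direction and was not tested. A true similarity of these ages may explain the values as well, and with 1 library it cannot be told apart from mixed labels.

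Other splits of the same samples were counted for the comparisons with at least 3 samples per group. For conduction against working regions the real split was the 1 of 100 that gave as many genes (698, highest other 246), and for the ventricle again 1 of 100 (821, highest other 129), so chance can be excluded for both. For nodal against His-Purkinje regions 3 of 100 splits, out of 120 possible, gave at least 35. This share lay under 0.05, but the splits not drawn could raise it, so chance is not excluded. A split of PRBB, LPF and RPF from the rest gave 338, which points to another structure among these regions. For Purkinje fibers against bundle branches (4 of 15 splits; 78, highest other 259 for PLBB and DLBB), left against right (7 of 10; 18, highest other 331 for PLBB, DLBB and DRBB) and proximal against distal (1 of 3; 80, highest other 72) the splits were too few for a share under 0.05. The splits with 259 and 331 genes, several times the real counts, point to a structure of the samples. Both put PLBB and DLBB on one side and PRBB, LPF and RPF on the other. PRBB, LPF and RPF also lay together in the split with 338.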

How the results depend on the processing

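The edgeR tests, the thinning, the negative-probe subtraction, the runs without PRBB, the centring, the runs of the 19 conduction ROIs without a block and the shortened marker lists were chosen after the data were seen. Depth limits the conduction ROIs most, where 0.609 to 38.3% of targets stood at 1 count. Over 75 gene counts under another setting, 48 stayed within 1.5 times the reported count, 13 fell below and 14 rose above that range. Of 2734 values of named genes, 2452 kept their direction and side of the threshold, 217 lost and 28 gained the call, and 37 changed direction. Of 207 list tests 157 were alike with an estimated correlation and 50 lost their call. The cause was not tested for the values that follow.

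Gene counts moved by over 1.5 times as follows. Conduction against working regions gave 306 thinned, 462 with negative-probe subtraction and 290 centred. Ventricular conduction against working ventricle gave 388 thinned and 420 centred. Nodal against His-Purkinje gave 182 with single ROIs, 189 with the block, 192 without it on the same ROIs, 58 without LNB and 70 with subtraction. SAN against the junction gave 47 under quantile normalization, 26 with the block and 41 in edgeR. His bundle against branches gave 36 in edgeR, 32 with subtraction and 7 without PRBB. Purkinje against branches gave 27 under quantile normalization, 122 with the block, 50 with subtraction and 268 without PRBB. Left against right gave 11 under quantile normalization and 28 with the block. Proximal against distal gave 21 under quantile normalization, 15 in edgeR, 46 with subtraction and 4 without PRBB. SAN against RA gave 13 under quantile normalization. No pairing by ROI number was seen. Residuals of equal and unequal numbers correlated between −0.0288 and 0.0288 over 36 pairs of regions, and 4 of 9 regions matched best with their own number. ROIs of a region differed by about the counting noise, so these correlations cannot exclude a pairing.

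With each ROI left out, counts ranged from 355 to 856 for conduction against working regions, 498 to 787 in the ventricle, 11 to 42 for nodal regions, 6 to 32 for SAN against the junction, 8 to 24 for His bundle, 21 to 111 for Purkinje fibers, 9 to 25 for left against right, 21 to 109 for proximal against distal and 7 to 9 for SAN against RA. Of 7234 such gene values 6733 kept direction and call, and 43 changed direction. Log2 changes that crossed 0 this way ranged, for conduction against working regions, from −0.0106 to 0.24 for Shox2 and −0.0886 to 0.13 for Tbx3, and in the ventricle from −0.22 to 0.0891 for Shox2. For His bundle against branches the ranges were −0.31 to 0.23 for Gja5, −0.18 to 0.12 for Irx3 and −0.23 to 0.86 for Tbx3. For Purkinje against branches they were −0.39 to 0.30 for Hcn4 and −0.0446 to 0.49 for Tbx3. For left against right they were −0.16 to 0.41 for Cntn2, −0.57 to 0.15 for Gja5, −0.0118 to 0.73 for Hcn4, −0.50 to 0.14 for Shox2 and −0.12 to 0.60 for Tbx3. For proximal against distal they were −0.00496 to 0.35 for Etv1, −0.43 to 0.69 for Hcn4 and −0.11 to 0.96 for Tbx3. For SAN against RA they were −0.38 to 0.59 for Cntn2, −0.55 to 0.0754 for Irx3 and −0.50 to 0.89 for Myl2.

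Single genes changed direction under other settings. Under quantile normalization Actc1 was 0.0926, Myh6 0.0382 and Myl2 0.23 for left against right. Actc1 was −0.14, Etv1 −0.10, Hcn4 −0.0498 and Myl2 −0.35 for proximal against distal. Gja5 was 0.0712, Irx3 0.0780, Myl2 0.18 and Tbx3 −0.0428 for His bundle, Myl2 −0.0429 for Purkinje fibers, Irx3 0.58 for SAN against RA, and Shox2 0.39 and Tbx3 0.36 in the ventricle. In edgeR Etv1 was −0.0572 and Hcn4 −0.11 for proximal against distal, and Nppa 0.40, Shox2 0.71 and Tbx3 0.0793 in the ventricle (against LENDO and IVSA alone). Without PRBB, Gja5 was 0.44 and Nppa 0.18 for His bundle, Gja5 0.34 and Irx3 −0.0193 for left against right, and Hba-a1 −0.54, Hbb-b1 −0.75, Hbb-b2 −0.46 and Irx3 0.14 for proximal against distal. Thinned, Gja5 was 0.22 for SAN against RA, and Shox2 0.33 and Tbx3 0.0158 in the ventricle. With subtraction, Hcn4 was 0.0814 for Purkinje fibers, Irx3 0.00 for SAN against RA, and Shox2 0.27 and Tbx3 0.21 in the ventricle. Centred, Shox2 was 0.22 in the ventricle, and without RA and SAN Tbx3 was −0.11 for conduction against working regions.

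Among 75 tests of single-cell markers in ROIs 60 were alike. With 20 genes per type, the camera direction changed for bundle branch markers in the junction (0.605) and bundle branches (0.605) and for His bundle markers in the junction (0.828). For bundle branch markers in the SAN (0.956) only the mean log2 change crossed 0, from −0.00933 to 0.119. For Purkinje markers in the junction the mean (−0.115 to 0.0253) and the median (−0.151 to 0.0488) crossed 0 with the camera direction unchanged. Their call was lost (camera adjusted p 0.0428 to 0.827). His bundle (0.0958) and Purkinje markers (0.0934) in the SAN and bundle branch (0.172) and Purkinje markers (0.0873) in Purkinje ROIs lost their calls, and bundle branch markers in the His bundle (0.0145) gained one, all as adjusted p. Without atrial, ventricular and sarcomere genes, Purkinje markers in the junction (0.126) and sinoatrial (0.0552) and atrioventricular markers (0.175) in Purkinje ROIs lost their calls, His bundle markers in the His bundle (0.0101) gained one, and the mean of Purkinje markers in bundle branches (0.421) went from 0.00885 to −0.0292 with the camera direction unchanged. With cells thinned to 4435 UMIs the log2 ratios of P4 to P1 were −1.60 for Hbb-bs and −1.30 for Gal, against −1.37 and −1.10.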

Other observations

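A metabolic contrast like that between conduction tissue and working ventricle was seen between the authors' cell types. These types were clustered from the same single-cell counts, so their differences give no separate support. Contractile cells, the type the authors set apart from the conduction types, had 24247 CPM summed over fatty acid oxidation genes, against 7119 in sinoatrial and 10240 in Purkinje cells. Fabp3, a member of that list and so no separate result, made up most of the sum in contractile cells. It reached 14194 CPM there against 1669 to 3931 in the conduction types. Mb reached 2689 CPM in contractile cells against 104 to 922. Igfbp5 had 747 CPM in sinoatrial, 680 in atrioventricular, 395 in His bundle, 313 in bundle branch and 335 in Purkinje cells, and 40.5 in contractile cells. Cacna2d2 was highest in bundle branch cells (432 CPM) and atrioventricular cells (331), against 9.19 in contractile cells. All these cells passed the same tdTomato gate, and no test was run within 1 library.

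Sinoatrial cells had 3424 CPM of mural and smooth muscle genes against 303 to 962 in the other types, with Tagln at 685 CPM among their markers. Bmp2 stood at 146 CPM in sinoatrial and 230 in atrioventricular cells. With 17 and 26 cells these levels rest on few cells. Among the ROIs, limma set 400 higher and 151 lower genes of the Purkinje component (4 ROIs) apart from the mean of the other conduction components, 7 and 62 of the SAN (2 ROIs), 3 and 23 of the junction (3 ROIs), 5 and 12 of the His bundle (2 ROIs) and 27 and 7 of the bundle branches (8 ROIs). Power differs with the number of ROIs, so these counts are not ranked. Transgene targets marked the reporter: tdTomato read 101 to 318 in conduction and 12.7 to 19.2 in working ROIs, and Cre 7.72 to 41.2 and 4.15 to 9.82. The EGFP target, which the stated genotype does not explain, read 12.9 to 48.2 in conduction and 5.61 to 10.8 in working ROIs.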
